A study of Homo sapiens with 2 samples.

How the data were processed

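The series has 2 GEO samples, a gene expression library and a hashtag (HTO) library, made from 1 pool of thawed H9-derived cardiomyocytes with a calcium reporter. Per the labels, the cells came from day 15 of differentiation, were blocked and stained with hashtag antibodies, and were captured with 10x Genomics reagents and sequenced on a NextSeq 500. The authors deposited 1 matrix of raw counts (UMIs) with 36601 genes and 13 hashtags for 24038 barcodes. Per the file headers it was made with Cell Ranger 4.0.0, and per the submitters' processing notes with the genome build hg38. The alignment settings, the gene annotation release and the rule by which barcodes were called as cells are not given in the sources used here. The matrix holds whole numbers, 311110726 gene UMIs and 9911316 hashtag UMIs in all.

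Barcodes with at least 500 genes, at least 1000 UMIs and at most 25% mitochondrial UMIs were kept, which removed 2415 and left 21623. Doublets were sought with Scrublet in scanpy 1.11.5, with an expected rate of 0.008 per 1000 barcodes. Its own threshold (0.517) marked 989 barcodes (4.57%), against an expected 19.2%, and these were removed, so doublets remain among the 20634 cells analysed. These cells held 284543094 UMIs in 28893 genes, 1000 to 115854 per cell, with a median of 2.75% mitochondrial UMIs.

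Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without readout, mitochondrial and ribosomal genes, were reduced to 30 principal components. Exact 15-nearest-neighbour graphs (umap-learn 0.5.12, scikit-learn 1.9.0) were clustered with leidenalg 0.10.2 at resolution 0.6, 5 iterations and seed 0. This gave 12 clusters. Clusters were named from 14 marker lists of 115 genes and the 10 leading genes of each, ranked by fold with 5 CPM added to both sides. Cardiomyocyte-like clusters were pooled and clustered again in the same way, giving 7 clusters. A cluster that the lists did not name was called by its leading genes.

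For each comparison, UMIs were summed over the cells of each side and expressed as CPM. A gene was measured when the higher side had at least 10 CPM and at least 10 counts, and was counted as higher or lower from a ratio of 1.5. Levels have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, at 95% (scipy 1.17.1, Python 3.11.15). A gene with 0 counts on a side was set against a floor of 3 counts. Since cells of 1 pool are not replicates, no test and no p-value was computed. The 16 readout lists held 270 genes: depolarising ion channels, potassium channels, calcium handling, gap junction and adhesion, surface markers, sarcomere isoforms, cardiac transcription factors, natriuretic peptides, retinoic acid response, oxidative and fatty acid metabolism, glycolysis, extracellular matrix, stress and immediate early, apoptosis and p53, S phase and G2M phase. Each list's median ratio was placed among 10000 random lists of the same size drawn from 20 expression bins. That percentile describes this library only.

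Genes were named by rule: up to 4 genes per list with the largest ratios past 1.5, the 5 protein-coding genes on each side with the largest ratio outside lists and clustering genes at 50 CPM or more, and a fixed set that included HCN4, KCNJ2, KCNJ3, KCNA5, CACNA1G, RYR2, GJA5, SIRPA, THY1, CD200, NPPA, NPPB, MYH6, MYH7 and TNNI3 throughout. Filters, lists, the kinds of comparison and this rule were fixed before the data were examined. The classes and clusters compared, and the cluster left out of comparisons, followed from the clustering. Positions are from GENCODE 29 on GRCh38, which held 34616 of the gene identifiers, and 10 gene symbols occur more than once in the matrix. None of the listed genes was absent.

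Surface gene shares and cells with at least 3 G2M genes were computed after thinning every cell to 3000 UMIs. Cells with fewer were left out: 370 of the cardiomyocyte-like cells and 1831 of all cells. A cell was given to a hashtag that held at least 70% of at least 20 hashtag UMIs. No label says what a hashtag marks, so hashtags were treated as unassigned samples and described by their values, range and median. Free RNA was gauged by the level of the 12 cardiomyocyte markers in other classes; no correction was applied.

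The ratio and its interval were tested on simulated data with the depths of cluster 2 and the other cardiomyocyte-like cells. Of 8231 genes, 200 were given true folds of 2, 4, 0.5 or 0.25, 50 genes each. All of these passed the 1.5-fold threshold and 0% of the 8031 unchanged genes did. Intervals covered the true ratio in 95.2% of genes. Both sides were drawn at random from 1 profile, the counting model that the intervals assume, so this checks the calculation only. The simulation held no variation between cells or hashtags, no free RNA, no doublets and no true fold near 1.5.

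Alternatives were other filters (none, or at least 1000 genes, 2000 UMIs and at most 15% mitochondrial), doublets kept, resolutions of 0.3 and 1.0, 3000 variable genes, 30 neighbours, readout genes allowed in clustering, another seed, TMM scaling (edgeR 4.0.16), other denominators, means of cells, no minimum CPM, a 2-fold threshold, other thinning depths and other hashtag rules. Raw reads, the spatial origin of hashtags, trajectories and graft or arrhythmia data were not used here. The labels give no treatment groups to compare.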

Results

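Human cardiomyocytes for heart repair are grown from pluripotent stem cells, and such preparations hold several kinds of cell. The deposited data describe 1 pool of H9 embryonic stem cell-derived cardiomyocytes that carry a fluorescent calcium reporter. The cells had been frozen at day 15 of differentiation, thawed, labelled with antibody-borne oligonucleotides (hashtags) and pooled before droplet capture. RNA and hashtag molecules were counted as unique molecular identifiers (UMIs) in 20634 cells, with a median of 11991 UMIs and 3439 genes per cell. The labels do not say which hashtag marked which sample, so all comparisons are between groups of cells within this pool and have no replicates. Intervals are exact, at 95%, and cover counting error only.

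Which cell classes made up the preparation? Cells with contractile genes were the majority: 15996 of 20634 cells (77.5%, 76.9 to 78.1) were cardiomyocyte-like, and 68.5% to 83.3% over filters and clustering settings. The 12 cardiomyocyte marker genes, which include the sarcomere genes TNNT2, TTN and MYBPC3, summed to 43734 CPM there (UMIs scaled to a common total) and to 8503 CPM or less in the 5 other classes that were compared. Stromal-like cells made up 7.26% (6.91 to 7.62) and expressed the fibrillar collagen genes COL3A1 at 1180.0 CPM and COL1A1 at 411 CPM. A class of 783 cells (3.79%, 3.54 to 4.06) that matched no marker list was called by its leading genes, WFDC2 and CLDN4, which encode a secreted protease inhibitor-like protein and a tight-junction claudin. It expressed the epithelial genes KRT19 at 881 CPM, EPCAM at 365 CPM and CDH1 at 117 CPM.

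Small classes had sharp marker profiles. Endoderm-like cells (313 cells, 1.52%, 1.35 to 1.69) expressed the fetal serum protein gene AFP at 6301 CPM and the apolipoprotein gene APOA1 at 4946 CPM. Epicardial-like cells (258 cells, 1.25%, 1.103 to 1.411) expressed the mesothelial genes WT1 at 133 CPM, ALDH1A2 at 144 CPM and BNC1 at 96.3 CPM, together with TBX18 at 228 CPM and TCF21 at 191 CPM. Endothelial-like cells (63 cells, 0.305%, 0.235 to 0.390) expressed the vascular genes EMCN at 714 CPM and CDH5 at 278 CPM, and the endodermal and endocardial regulator SOX17 at 944 CPM. A further 1723 cells (8.35%, 7.98 to 8.74) formed a cluster with a median of 1940 UMIs and 13.1% mitochondrial UMIs, led by nuclear RNAs such as MALAT1 and NEAT1. Its cardiomyocyte markers summed to 36535 CPM, with single markers at 28.6% to 302% of their cardiomyocyte-like level (median 102%). It was given to no class and is not counted in the 77.5%. That cluster was left out of both sides of every comparison.

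**Figure D1:**
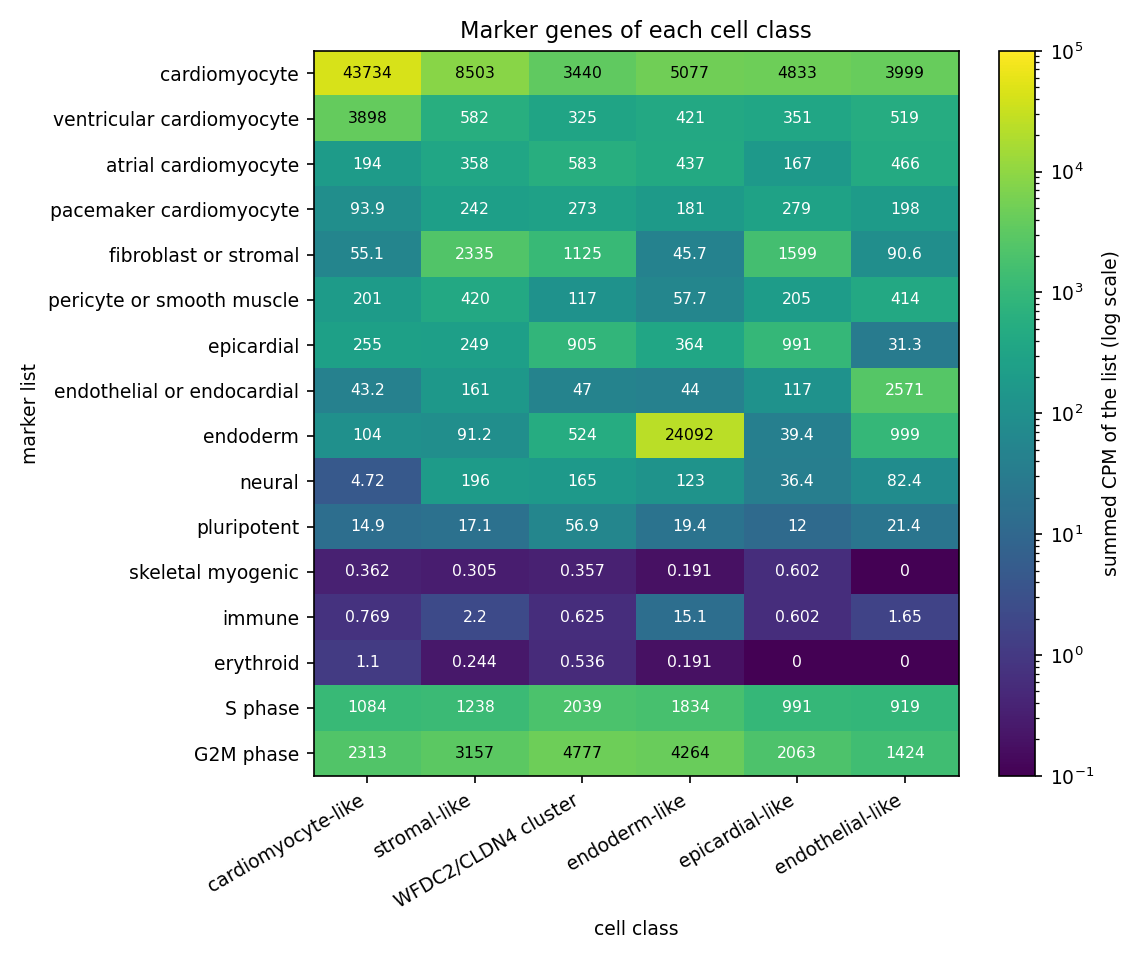
Summed CPM of each list of marker genes (vertical axis) in 6 cell classes (horizontal axis), with colour on a log scale and each value printed. The cardiomyocyte list reached 43734 CPM in cardiomyocyte-like cells, the endoderm list 24092 CPM in endoderm-like cells, and the skeletal, immune and erythroid lists at most 15.1 CPM in any class.

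Fibroblast or stromal genes summed to 2335 CPM in stromal-like and 1599 CPM in epicardial-like cells, against 55.1 CPM in cardiomyocyte-like cells. Pericyte or smooth muscle genes were less selective, with 420.2 CPM in stromal-like and 201 CPM in cardiomyocyte-like cells. Epicardial genes reached 991 CPM in epicardial-like cells and 905 CPM in the WFDC2/CLDN4 cluster, the latter largely through KRT19. Endothelial or endocardial genes summed to 2571 CPM in endothelial-like cells and endoderm genes to 24092 CPM in endoderm-like cells. Neural genes were highest in stromal-like cells, at 196 CPM, and pluripotency genes in the WFDC2/CLDN4 cluster, at 56.9 CPM. The pluripotency factor genes POU5F1 and NANOG had 14 counts each over the 5 other classes together. They gave little of that sum, which therefore does not mark pluripotent cells. Ventricular genes summed to 3898 CPM in cardiomyocyte-like cells, of which MYL3 alone gave 3384 CPM, and to 325 to 582 CPM in the 5 other classes. The atrial and pacemaker lists did not mark cardiomyocyte-like cells, with 194 and 93.9 CPM there against 167 to 583 CPM and 181 to 279 CPM in the others.

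Did cells outside the cardiomyocyte class differ in excitability genes? HCN4, which encodes the pacemaker channel, stood at 63.0 CPM in cardiomyocyte-like cells and 16.4 CPM in the 2915 cells of the 5 other classes, 3.84-fold higher (3.54 to 4.17). The sarcoplasmic calcium release channel gene RYR2 was 4.82-fold higher (4.59 to 5.06) and the atrial natriuretic peptide gene NPPA 10.6-fold higher (10.1 to 11.2). The gene for the inward rectifier KCNJ2, which holds the resting potential, was lower in cardiomyocyte-like cells by 59.7-fold (42.2 to 86.8), at 0.148 against 8.84 CPM. The WFDC2/CLDN4 cluster, at 23.5 CPM, gave 263 of the 325 KCNJ2 counts of the other classes. Endothelial-like cells had a similar level from few counts, while stromal-like cells had 2.50 CPM, endoderm-like cells 1.14 CPM and epicardial-like cells 0 counts. THY1, a surface glycoprotein of stromal and vascular cells, was lower by 59.1-fold (50.9 to 69.0).

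By gene list, 7 of 8 measured depolarising ion channel genes were at least 1.5-fold higher and 0 lower in cardiomyocyte-like cells, among them CACNA1G (3.28-fold) and CACNB2 (5.16-fold). Of 5 measured potassium channel genes, 3 were higher, including the repolarising channel gene KCNH2 (4.03-fold) and KCNJ5 (4.55-fold), and 1 was lower. KCNJ2 and KCNJ3 were below the 10 CPM minimum and are not among the 5, with KCNJ3 at 5.19 against 5.28 CPM. Calcium handling genes were higher in 8 and lower in 2 of 11, with TRDN 6.62-fold higher and the inositol trisphosphate receptor gene ITPR2 5.30-fold lower. Sarcomere isoforms were higher in 9 and lower in 1 of 11: MYH7 by 9.23-fold, MYH6 by 7.34-fold and TCAP by 10.4-fold, whereas the slow skeletal troponin gene TNNT1 was 14.3-fold lower. Cardiac transcription factor genes were higher in 6 and lower in 0 of 13, with NKX2-5 4.85-fold and TBX5 3.26-fold higher. Both natriuretic peptide genes were higher. Medians of the depolarising channel, potassium channel, calcium handling, sarcomere, oxidative and glycolysis lists each lay above all 10000 matched random lists. The class was named from contractile genes and the random lists were matched on expression only. High ranks of heart muscle lists therefore describe the class and are not separate evidence for its name.

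Metabolic genes followed the contractile genes. Glycolysis genes were higher in 13 and lower in 1 of 15, such as PFKP (4.74-fold) and HK1 (2.86-fold), and oxidative and fatty acid genes were higher in 7 and lower in 0 of 10, such as COX6A2 (11.98-fold) and FABP3 (7.22-fold). Extracellular matrix genes went the other way, higher in 2 and lower in 9 of 14: the proteoglycan gene BGN was 53.3-fold, HAPLN1 33.9-fold and fibronectin (FN1) 15.1-fold lower. Of 13 surface marker genes 4 were higher, including VCAM1 (5.45-fold), CORIN (6.98-fold) and SIRPA (3.15-fold), and 5 were lower, including CD200 (6.87-fold). Gap junction and adhesion genes were mixed, with 2 higher and 2 lower of 7; the connexin 43 gene GJA1 was 1.99-fold lower and plakophilin PKP2 2.10-fold higher. Retinoic acid response genes were higher in 0 and lower in 3 of 6, CRABP1 by 14.1-fold. Stress genes were higher in 3 and lower in 4 of 15, and apoptosis genes higher in 1 (CDKN1A, 2.46-fold) and lower in 1 (PMAIP1, 12.6-fold) of 7. Against the pooled other classes, cell cycle genes were lower in cardiomyocyte-like cells: 16 of 33 S phase and 37 of 52 G2M genes, and 0 higher. Fewer phase genes passed the threshold with TMM scaling.

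Outside the lists, the muscle genes APOBEC2 (11.5-fold), MB (10.8-fold) and HSPB7 (8.34-fold) led the higher genes, and the repressor gene TLE1 (33.0-fold) and actin-binding TAGLN2 (31.8-fold) the lower ones. In total 67 readout genes were higher and 82 lower of 222 measured, or 67 and 29 of 137 without the phase lists. Scaling by TMM moved the median log2 ratio of all genes from -0.19 to 0.25 and the split to 86 higher and 45 lower, or 84 and 20 without the phase lists, so many of the lower calls among phase genes ended. Transcripts of the 12 cardiomyocyte markers reached a median of 15.5% of their cardiomyocyte-like level in the other classes. Free RNA, undetected doublets and true expression were not separated, so small residual levels of cardiac genes there are not read as expression.

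Each other class was then set against cardiomyocyte-like cells. Stromal-like cells had THY1 at 68.1 against 0.794 CPM, 85.7-fold higher (73.5 to 100.0), BGN 97.1-fold higher (76.5 to 125) and FN1 19.4-fold higher (18.8 to 20.0). Matrix genes were higher in 8 and lower in 1 of 14, retinoic acid response genes higher in 5 and lower in 0 of 7 (CRABP1 24.0-fold, STRA6 3.96-fold), and G2M genes higher in 24 and lower in 0 of 51. All but 1 of 15 glycolysis genes were lower and 0 higher. The developmental regulator FOXC1 (33.4-fold) and the microfibril gene MFAP4 (19.1-fold) were among the higher genes outside the lists. In this class 66 readout genes were higher and 63 lower of 220, or 35 and 62 of 139 without the phase lists. The split was 32 and 85 with TMM scaling and 37 and 101 with the strict filter. Under each of these settings fewer phase genes were higher, so the G2M count depends on the processing.

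The WFDC2/CLDN4 cluster had KCNJ2 at 23.5 against 0.148 CPM, 159-fold higher (112 to 231), and KCNMA1, the large-conductance calcium-activated potassium channel gene, 135-fold higher (113 to 163). HCN4 was 10.5-fold lower (8.29 to 13.6). The vesicle traffic gene RAB25 was 168-fold (144 to 197) and the epithelial transcription factor gene GATA3 53.3-fold higher. Cell cycle genes were higher in 28 of 36 (S) and 46 of 52 (G2M) with 0 lower in either list, and 11 of 12 cardiac transcription factor genes were lower. Of the glycolysis genes 13 of 15 were lower, but the glucose transporter gene SLC2A3 was 4.05-fold higher (3.96 to 4.15), at 717 against 177 CPM. The class had 106 readout genes higher and 84 lower of 226, 32 and 84 of 138 without the phase lists, and 84 and 95 with TMM scaling.

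Endoderm-like cells had high levels of liver-type genes outside the lists, with plasminogen (PLG) 487-fold (323 to 767) and the bile acid enzyme gene AKR1D1 336-fold higher (253 to 454). The surface glycoprotein gene CD24 stood at 1068 against 130 CPM, 8.24-fold higher (8.01 to 8.48), and the stress-induced cytokine gene GDF15 was 6.61-fold higher. G2M genes were higher in 44 and lower in 0 of 52, while 10 of 10 sarcomere and 15 of 15 glycolysis genes were lower. The class had 76 readout genes higher and 94 lower of 216, 11 and 94 of 129 without the phase lists, and 61 and 101 with TMM scaling.

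Epicardial-like cells had TNNT1 at 699 against 6.96 CPM, 100.4-fold higher (94.3 to 107), and the immunoregulatory surface gene CD200 at 113 against 3.99 CPM, 28.2-fold higher (24.98 to 31.83). The matrix genes SMOC2 (357-fold) and SPARC (18.5-fold) were higher, and 7 of 13 matrix genes were higher and 2 lower. GJA1 was 4.31-fold higher (3.91 to 4.74), whereas NKX2-5 was 20.9-fold lower (17.1 to 25.8). Cell cycle genes were mostly level, with 1 higher and 6 lower of 47 G2M and 3 higher and 2 lower of 27 S phase genes. The class had 25 readout genes higher and 90 lower of 208, 21 and 82 of 134 without the phase lists, and 22 and 103 with TMM scaling.

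Endothelial-like cells had the ecto-nucleotidase gene NT5E 594-fold (362 to 986) and THY1 492-fold higher (405 to 598), the VEGF receptor gene KDR at 694 against 24.9 CPM, and KCNJ2 167-fold higher (84.9 to 313). The cardiac and endothelial cofactor HOPX was 24.7-fold higher. KCNJ5 had 0 counts and was at least 3.73-fold lower than in cardiomyocyte-like cells. Apoptosis and p53 genes were higher in 6 and lower in 0 of 8. Cell cycle genes were lower than in cardiomyocyte-like cells in 28 of 48 (G2M) and 12 of 25 (S), with 1 higher in each list. From 63 cells, 36 readout genes were higher and 120 lower of 212, 34 and 80 of 139 without the phase lists, and 36 and 131 with TMM scaling.

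Were cardiomyocyte-like cells uniform in the genes that set rhythm? They formed 7 clusters, and fewer than 2 could be given a chamber name under the naming rule, so each was set against all other cardiomyocyte-like cells by its number. Cluster 2 (2397 cells, 15.0% of cardiomyocyte-like cells, 14.4 to 15.5, and 13.7% to 20.3% over filters and clustering settings) had the atrial regulator NR2F2 at 301 CPM and the sinus node regulator SHOX2 at 41.1 CPM, against 8.86 CPM for NR2F2 in cluster 1. The ventricular regulators HEY2 and IRX4 stood at 20.9 and 25.9 CPM in cluster 2 and at 209 and 116 CPM in cluster 1. Summed atrial genes were 636 against 131 CPM, pacemaker genes 239 against 51.6 CPM and ventricular genes 2247 against 4352 CPM in clusters 2 and 1. Cluster 1 had the lowest atrial and pacemaker sums of the 7 clusters, so these contrasts are the widest. NR2F2 and PAM (244 against 97.3 CPM) made up most of the atrial sum in cluster 2. HEY1 (16.6 against 16.8 CPM), DHRS9 (0.917 against 1.13 CPM) and TBX18 (9.22 against 11.7 CPM) were not higher than in cluster 1. The other atrial and pacemaker genes were higher. MYL3 alone gave 2021 of the 2247 and 3801 of the 4352 CPM of the ventricular sums. These markers helped to form the clusters, whereas the readout genes below did not.

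HCN4 stood at 157 CPM (152 to 163) in cluster 2 and 53.7 CPM in other cardiomyocyte-like cells, 2.93-fold higher (2.82 to 3.04). The L-type calcium channel gene CACNA1D, which opens at negative potentials in pacemaker cells, was 4.08-fold higher (3.86 to 4.31), at 85.2 against 20.9 CPM. GJA1, the connexin of fast ventricular coupling, was 3.77-fold lower (3.27 to 4.36). NPPA was 9.45-fold (9.34 to 9.57) and the skeletal actin gene ACTA1 8.35-fold higher (8.14 to 8.56). In GENCODE 29 (GRCh38) these genes lie at 73319859 to 73369264 on chromosome 15 (HCN4), 53328963 to 53813733 on chromosome 3 (CACNA1D), 121435577 to 121449727 on chromosome 6 (GJA1) and 11845709 to 11848345 on chromosome 1 (NPPA).

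**Figure D2:**
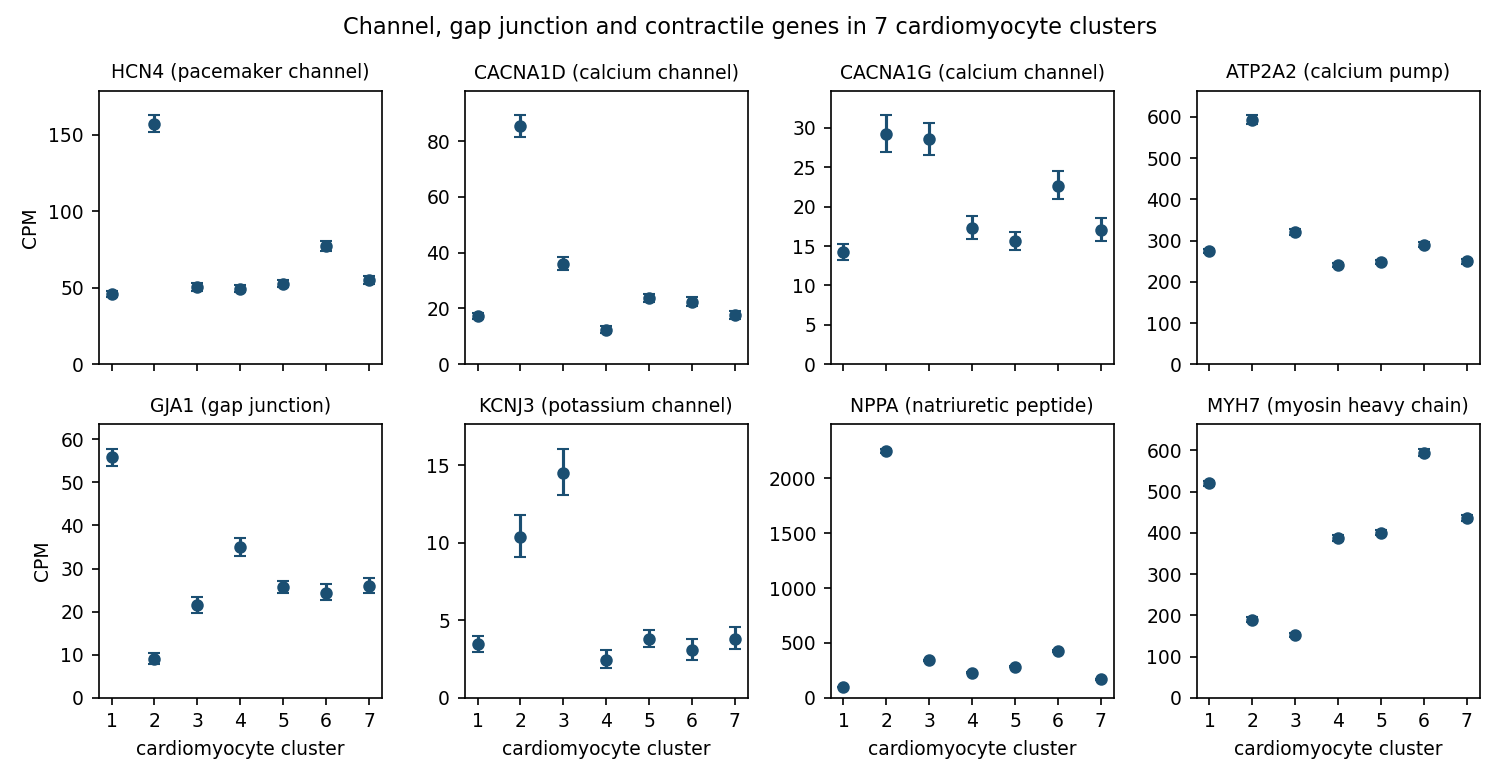
CPM (vertical axes, from 0) of 8 genes in the 7 cardiomyocyte clusters (horizontal axis); points are pooled counts of each cluster and bars are exact 95% Poisson intervals. HCN4 reached 157 CPM in cluster 2, GJA1 55.8 CPM in cluster 1 and KCNJ3 14.5 CPM in cluster 3.

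In cluster 2, depolarising channel genes were higher in 6 and lower in 1 of 9. CACNA1G (1.61-fold) and CACNA1C (1.58-fold) were among the higher, and both were below 1.5 with TMM scaling. Calcium handling genes were higher in 3 and lower in 0 of 10: the calcium pump gene ATP2A2 by 2.21-fold, the exchanger gene SLC8A1 by 2.02-fold and JPH2 by 1.95-fold, while RYR2 was within the threshold at 1.16-fold. Potassium channel genes were higher in 2 and lower in 0 of 7, KCNJ3 by 2.22-fold and KCNIP2 by 1.81-fold. Sarcomere genes were higher in 6 and lower in 1 of 11: TNNI3 by 2.23-fold and MYH6 by 1.81-fold, against MYH7, which was 2.27-fold lower. Matrix genes were higher in 5 and lower in 1 of 12 (COL5A2 and COL6A2 2.86-fold each), and surface genes higher in 5 and lower in 2 of 12, with PDGFRA 3.28-fold and CD200 3.64-fold higher and ALCAM 1.87-fold lower. Transcription factor genes were higher in 3 and lower in 1 of 12 (TBX5 2.42-fold higher, HAND1 2.26-fold lower). Stress and immediate early genes were higher in 2 and lower in 3 of 15. ATF3 (4.21-fold) and HSPA1A (1.66-fold) were higher, and HSPH1 (1.72-fold), EGR1 (1.65-fold) and FOSB (1.52-fold) lower. G2M genes were lower in 39 and higher in 0 of 47. Among cells of 6000 to 12000 UMIs, 13 of the 37 higher genes outside the phase lists were below 1.5, among them JPH2 (1.43), MYH6 (1.49), CACNA1G (1.25) and the matrix genes SPARC (1.41) and FN1 (1.37).

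Without the phase lists 37 genes were higher and 13 lower of 133; with them 38 and 61 of 207, or 30 and 75 with TMM scaling and 42 and 20 when the proliferating cluster 5 was left out of the other side. Among genes outside the lists the glycan enzyme gene EXT1 (2.81-fold) and the sarcomere-associated TRIM55 (2.44-fold) and NEXN (2.29-fold) led the higher ones, and the growth factor gene PDGFD (4.10-fold) and the junction gene MYZAP (3.20-fold) the lower ones. Cluster 2 took unequal shares from the hashtags, so ratios were also taken within the 10 hashtags that had at least 20 cells on both sides. HCN4, CACNA1D, ATP2A2, TBX5 and NPPA were higher in 10 of 10 hashtags, with median folds of 2.49, 3.92, 2.44, 1.94 and 11.045. GJA1 was lower in 9 of 10 and MYH7 in 8 of 10, whereas CACNA1G was higher in 8 of 10 at a median of 1.25-fold and TBX20, 1.57-fold higher in the pool and below 1.5 with TMM scaling, was higher in 4 of 10.

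Cluster 3 (2277 cells, 14.2%, 13.7 to 14.8, and 10.2% to 24.99% over filters and clustering settings) had the G protein-gated potassium channel gene KCNJ3 at 14.5 against 4.08 CPM, 3.56-fold higher (3.15 to 4.02), and the adhesion gene ALCAM 3.21-fold higher (3.08 to 3.36). MYH7 was 2.90-fold lower (2.809 to 2.996), the brain natriuretic peptide gene NPPB 4.08-fold lower (3.96 to 4.20) and the endoglin gene ENG 3.50-fold lower (3.08 to 3.98). CACNA1G was 1.59-fold higher (1.46 to 1.72), but below 1.5 with TMM scaling. Its leading gene was the ventricular marker IRX1, at 132 CPM against 18.2 CPM in other cardiomyocyte-like cells. The ventricular markers HEY2 and IRX4 stood at 131 and 115 CPM, against 166 and 109 CPM in all cardiomyocyte-like cells. Within hashtags HEY2 was lower in cluster 3 in 9 of 10 (median ratio 0.781) and IRX4 in 6 of 10 (0.988). Neither marker was therefore raised in cluster 3 as IRX1 was. Its pacemaker marker genes summed to 158 CPM, mostly CPNE5 at 87.2 CPM and TBX3 at 53.6 CPM. Every other gene of that list, SHOX2 among them (1.20 CPM), was at 6.12 CPM or less. Retinoic acid response genes were higher in 3 and lower in 1 of 5 (among them RARB 1.87-fold and CRABP2 1.76-fold higher, DHRS3 1.96-fold lower), with a list median of 1.61 at percentile 99.99 of matched lists. The gene at that median, 1 of the 3, was below 1.5 with TMM scaling. Calcium handling genes were higher in 2 and lower in 0 of 10, TRDN by 1.89-fold and HRC by 1.54-fold, the latter below 1.5 with TMM scaling. Of the transcription factor genes TBX2 was 1.93-fold higher, and HAND1 (2.01-fold), HAND2 (1.80-fold) and TBX20 (1.68-fold) were lower.

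Within hashtags, KCNJ3, ALCAM and CACNA1G were higher in 10 of 10, with medians of 6.56-, 2.77- and 1.81-fold, MYH7 was lower in 9 of 10, and NPPB in 8 of 10 at a median of 2.72-fold, with 1 hashtag 4.09-fold higher. Outside the lists the transaminase gene ABAT (3.08-fold) and the sorting receptor gene SORCS1 (2.68-fold) led the higher genes and the Wnt inhibitor gene TMEM88 (2.76-fold) the lower ones. Without the phase lists 16 genes were higher and 13 lower of 128. At resolution 0.3 the split with phase lists went from 16 higher and 66 lower to 6 and 72, and with TMM scaling to 10 and 77.

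Other clusters differed in metabolism, cycling and peptide genes. In clusters 1, 4, 6 and 7 most of the lower readout genes were phase genes, with the proliferating cluster 5 on the other side. Cluster 1 (3629 cells, 22.7%) had GJA1 at 55.8 against 24.6 CPM, 2.27-fold higher (2.17 to 2.38), and the calcium-activated potassium channel gene KCNN2 1.58-fold higher, while NPPA was 5.12-fold, ACTA1 4.14-fold and NPPB 4.11-fold lower; 2 readout genes were higher and 75 lower of 204, or 2 and 20 of 129 without the phase lists. Cluster 4 (2240 cells, 14.0%) had glycolysis genes higher in 9 and lower in 0 of 15, with LDHA 2.03-fold (2.01 to 2.05) and ENO1 1.98-fold higher, and the hypoxia-inducible genes BNIP3 (2.11-fold) and VEGFA (1.86-fold) were higher as well; its split was 20 higher and 67 lower of 202, or 20 and 9 of 129 without phase lists. Cluster 6 (1736 cells, 10.9%) had KDR 2.65-fold (2.50 to 2.81), ENG and NPPB each 2.35-fold and the Z-disc gene TCAP 1.82-fold higher, with 11 genes higher and 49 lower of 203, or 11 and 3 of 130 without phase lists. Its leading gene was the endoderm marker SERPINA1 (38.6 against 10.7 CPM), and 38.8% of its cells had 1 hashtag, the lowest share of the 7 clusters. Cluster 7 (1709 cells, 10.7%), in which metallothionein genes led, had ENG 1.63-fold higher and NPPA 2.66-fold lower, with 1 gene higher and 60 lower of 200, or 1 and 7 of 127 without phase lists. The endoderm markers TTR (9.95 against 0.543 CPM) and SERPINA1 (28.03 against 11.9 CPM) were also among its leading genes. Doublets and free RNA were not separated from expression in clusters 6 and 7. Ratios within hashtags were taken for clusters 2 and 3 only, so differences between the hashtagged samples were not separated from the ratios of the other clusters.

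Cluster 5 (2008 cells, 12.6%, 12.04 to 13.08, and 12.57% to 16.8% over filters and clustering settings) held the proliferation genes. The centromere histone gene CENPA was 56.5-fold (48.6 to 65.9), the mitotic kinase gene NEK2 49.4-fold and the ubiquitin conjugase gene UBE2C 49.3-fold higher than in other cardiomyocyte-like cells. G2M genes were higher in 52 and lower in 0 of 52 and S phase genes higher in 37 and lower in 0 of 39. TCAP was 2.06-fold, TNNI3 1.83-fold, HRC 1.76-fold and the calcium pump regulator PLN 1.60-fold lower, and 8 readout genes were lower in all, a count that was 13 to 18 under 6 of the alternatives. Phase genes summed to 7545 CPM (G2M) and 2453 CPM (S) there, to 2313 and 1084 CPM in all cardiomyocyte-like cells, to 3157 and 1238 CPM in stromal-like cells and to 4777 and 2039 CPM in the WFDC2/CLDN4 cluster.

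Surface genes matter because a sort acts on their proteins. The shares below count cells with detected RNA and rise with depth, so they do not give shares of cells with the surface protein. With every cell thinned to 3000 UMIs, SIRPA, a surface receptor used to enrich cardiomyocytes, had a UMI in 8.0% (7.58 to 8.44) of cardiomyocyte-like cells and in 2.60% (1.83 to 3.58) of stromal-like cells, whose median depths before thinning were 12982 and 10253 UMIs. THY1 had a UMI in 60.0% (46.5 to 72.4) of endothelial-like, 13.7% (11.9 to 15.6) of stromal-like and 11.4% (7.698 to 16.03) of epicardial-like cells. In cardiomyocyte-like cells the share was 0.173% (0.114 to 0.251), where free RNA, doublets and low expression were not separated. CD200 had a UMI in 27.6% (22.2 to 33.7) of epicardial-like cells, 6.65% (5.39 to 8.09) of stromal-like cells and 3.46% (2.75 to 4.29) of cluster 2, against 1.41% (1.23 to 1.61) of all cardiomyocyte-like cells and 0.684% (0.439 to 1.02) of cluster 1. Without thinning the SIRPA share was 31.5% in cardiomyocyte-like and 9.55% in stromal-like cells.

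How many cells carried G2M transcripts was asked in the same thinned cells. At least 3 G2M genes were detected in 53.3% (52.5 to 54.1) of cardiomyocyte-like, 60.1% (57.5 to 62.7) of stromal-like, 76.3% (73.1 to 79.3) of WFDC2/CLDN4 and 77.3% (72.1 to 82.0) of endoderm-like cells. Cluster 5 reached 96.7% (95.8 to 97.4) and cluster 4, with the lowest G2M level, 36.2% (34.2 to 38.2). Because the share was that high in clusters with low G2M levels, the rule does not isolate cycling cells and free RNA remains open as a contributor. At 5 genes the shares were 21.5% in cardiomyocyte-like cells, 90.6% in cluster 5 and 5.83% in cluster 4.

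The 13 hashtags were unassigned samples, and their counts show how far the classes varied among them. A single hashtag held at least 70% of at least 20 hashtag UMIs in 10001 cells (48.5%), giving 396 to 1327 cells per hashtag with a median of 728. Cardiomyocyte-like cells made up 30.6% to 89.7% of a hashtag's cells (median 84.5%), stromal-like cells 1.82% to 31.1% (median 6.41%), endoderm-like cells 0.166% to 8.60% (median 0.323%) and the WFDC2/CLDN4 cluster 0.312% to 30.3% (median 0.822%). Cluster 2 made up 1.14% to 73.8% of a hashtag's cardiomyocyte-like cells (median 8.38%) and cluster 3 1.61% to 61.9% (median 4.67%). The proliferating cluster 5 varied less, from 6.35% to 22.2% (median 11.3%).

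**Figure D3:**
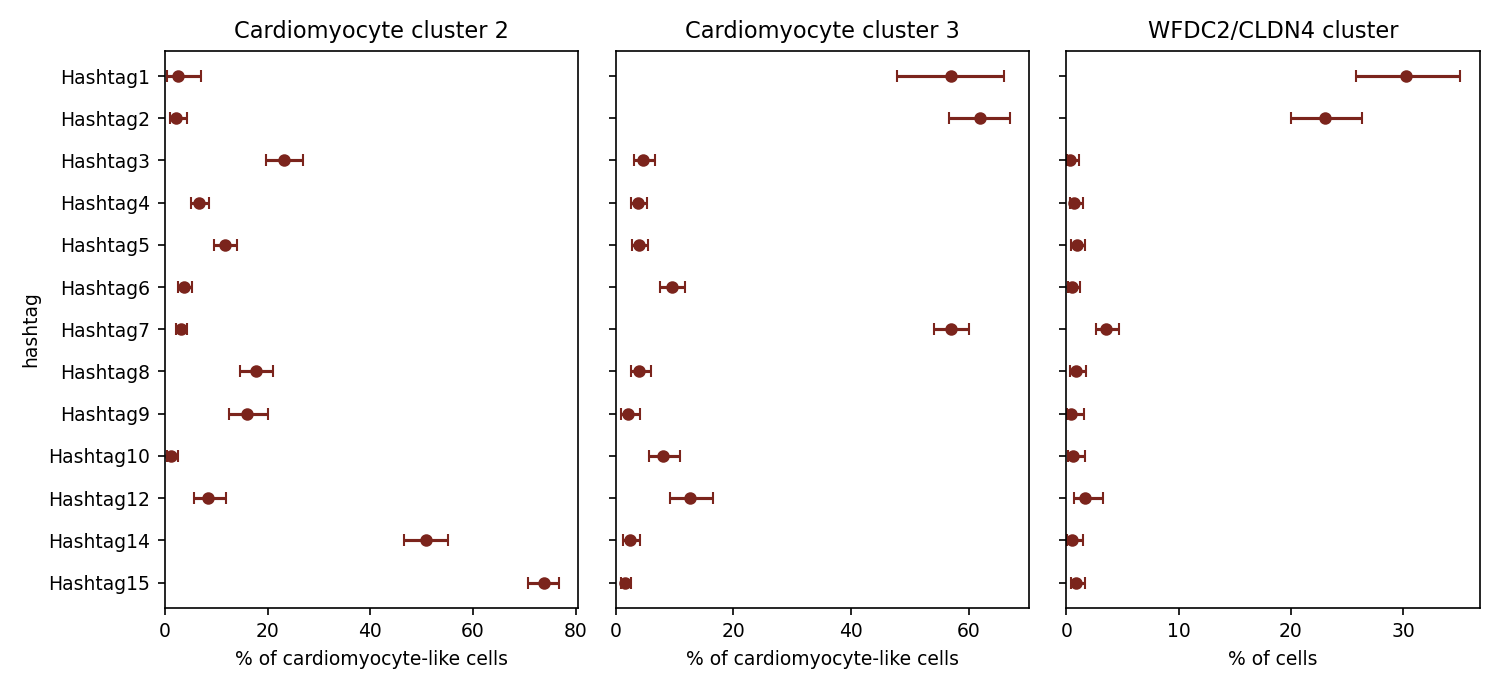
Share of cluster 2 and cluster 3 among cardiomyocyte-like cells and of the WFDC2/CLDN4 cluster among all cells (horizontal axes, percent) for each of 13 hashtags (vertical axis); bars are exact 95% binomial intervals. Cluster 2 reached 73.8% in Hashtag15 and 50.9% in Hashtag14 and stayed at or below 23.2% in the others.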

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

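Among the tests in this part, the repeat at 90% of hashtag UMIs, the comparison with the share in the pool, the ratios within hashtags and the split of the counts were chosen only after the result was seen. The hashtag counts lie outside the comparisons of cell classes, and the shares of classes differed between hashtags. Cluster 2 made up 73.8% (70.8 to 76.7) of the cardiomyocyte-like cells of Hashtag15. Cluster 3 made up 61.9% (56.7 to 66.9) of those of Hashtag2, with 57.0% in each of Hashtag1 and Hashtag7. The WFDC2/CLDN4 cluster, with its high KCNJ2, KRT19 and cell cycle genes, made up 30.3% (25.8 to 35.1) of all cells of Hashtag1. No biological explanation was tested for any of these, since the labels give no groups of hashtags.

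Cells with NR2F2, SHOX2 and high HCN4 were unevenly spread over the hashtags, and depth is a candidate explanation because cluster 2 had a median of 8381 UMIs. Among cells with 6000 to 12000 UMIs, the highest share, 82.6% (lower bound 79.0%), was 5.01 times the median of 16.5% over 13 hashtags. Without this limit the factor was 8.81, with a median of 8.38%. The value passed its preset bound of 5 only narrowly and lies above the factor of 3 below which depth would have accounted for the spread, which argues against depth as the whole cause and leaves it open as a part. Cells given to the wrong hashtag at random bring the mixture of the pool, with 15.0% in cluster 2, and cannot have made a share with a lower bound of 70.8%. Errors that favour some cells stay open: the highest share was 81.8% when 90% of hashtag UMIs were asked for, but the median was then 14.3%, so the stricter call favoured cluster 2 in general and decides nothing. Differences between the hashtagged samples in culture or cell line handling stay open and untested.

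A further pattern was the set of 37 readout genes, without phase genes, that were higher in cluster 2, among them HCN4, CACNA1D and NPPA. If a few hashtagged samples had fed the cluster and carried these levels with them, the ratios would vanish within correctly called hashtags. Of the 37 genes, 33 kept a median ratio of at least 1.5 over 10 hashtags and 36 stayed above 1. Cells of such samples called to other hashtags would keep the ratios too. Errors of that kind stay open above, so the test cannot exclude this explanation. When clusters came from a random part of the UMIs and ratios from the rest, 36 of 37 kept 1.5, which decides nothing, because these genes had been kept out of the clustering and the outcome was fixed in advance. In cells of 6000 to 12000 UMIs, 24 of 37 kept 1.5, and 37 of 37 stayed above 1 (1423 against 4130 cells). Depth therefore may add to part of the 13 others, such as MYH6 (1.49) and KDR (1.03), and the parts cannot be told apart at this bound, while HCN4 (2.51) and CACNA1D (3.49) kept most of their fold.

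The last pattern was that 10633 cells (51.5%) had no hashtag with 70% of the hashtag UMIs. Barcodes with cells of a pair of hashtags would give the second hashtag most of the remaining UMIs and more RNA. The second held a median of 34.0% of the UMIs outside the first, and median gene UMIs were 12462 against 11591, a ratio of 1.08, which argues against such barcodes as the main source. Few hashtag UMIs stay open: these cells had a median of 137 hashtag UMIs against 297, a ratio of 0.461, consistent with weak staining against a constant background.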

How the results depend on the processing

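The tests chosen only after the result was seen are those on cells with 1 hashtag, without cluster 5, without cluster 6 and without each hashtag. Main values are 77.5% cardiomyocyte-like and 7.26% stromal-like cells, and 15.0%, 14.2% and 12.6% of cardiomyocyte-like cells in clusters 2, 3 and 5. Of the main results, 235 count values stayed within 1.5 times the main count and 17 did not, and 68 shares stayed within their interval and 72 did not. Among the other results 475 counts stayed within that factor and 58 did not, and 142 shares stayed within their interval and 73 did not. Of the ratios of named genes 4264 stayed within their interval, 1474 moved beyond it with the same direction or without having passed the threshold, and 4 reversed.

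Cluster shares depended on the filters and clustering settings. Shares of clusters 2, 3 and 5 were 17.1%, 10.2% and 16.5% with 30 neighbours (stromal-like 7.89%), 18.1%, 10.9% and 14.6% with 3000 variable genes, and 18.4%, 10.6% and 14.4% with readout lists allowed. At resolution 0.3 they were 17.8%, 24.99% and 14.03% (stromal-like 8.83%). At resolution 1.0 clusters 2 and 3 were 17.5% and 11.8%, cardiomyocyte-like cells 76.7% and stromal-like cells 7.89%. With seed 1, clusters 2 and 5 were 15.9% and 14.8%. The strict filter gave 20.3%, 10.4% and 16.8%, with 83.3% cardiomyocyte-like and 6.78% stromal-like cells. No filter gave 18.2%, 11.17% and 16.015%, with 68.5% and 6.28%. With doublets kept, clusters 2 and 5 were 13.7% and 13.6%, and the classes 75.9% and 8.90%. With only cells with 1 hashtag the clusters were 18.97%, 15.63% and 11.8%, and stromal-like cells 8.19%. Without cluster 6 they were 16.81%, 15.97% and 14.08%, with 75.5% and 7.93%. Fewer cells explain the shift without cluster 6; for the others the cause was not tested.

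Counts of genes held under most settings. At 2-fold, cluster 2 had 20 higher genes (38 at 1.5-fold), cluster 3 had 3 (16), cardiomyocyte-like cells 43 lower (82) and cluster 5 2 lower (8), by construction. With TMM, cluster 3 had 10 higher and cardiomyocyte-like cells 45 lower. With no minimum CPM, cluster 2 had 93 lower (61) and cluster 5 18 lower, more genes being measured. Lower genes of cluster 5 numbered 14 with the mean of per-cell CPM, 14 with totals without mitochondrial, ribosomal and sarcomere genes, 14 with only cells with 1 hashtag, 16 with no filter and 13 at resolution 1.0. Cluster 3 had 6 higher genes at resolution 0.3. Without cluster 5, lower genes numbered 20 in cluster 2 and 17 in cluster 3 (66), since the proliferating cells had left the other side. The genes HK2 (0.909) and GADD45B (0.965) reversed in cluster 3 at resolution 0.3, and CENPA (1.01) and RAD51AP1 (1.55) in cluster 2 without cluster 5.

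Shares of cells with a UMI followed depth. Cardiomyocyte-like cells with G2M genes were 53.3% at 3000 UMIs, 35.1% thinned to 2000, 79.2% thinned to 5000, 95.8% when not thinned and 21.5% with at least 5 genes. CD200 in cluster 2 was 3.46%, then 2.46%, 5.14% and 9.14% at 2000, 5000 and not thinned. In the same order SIRPA in cardiomyocyte-like cells was 8.0%, 5.70%, 12.9% and 31.5%, and THY1 in stromal-like cells 13.7%, 10.3%, 20.1% and 28.6%. Cells with 1 hashtag were 48.5%, then 78.9% at 50% of hashtag UMIs, 12.5% at 90% and 47.5% with at least 100 hashtag UMIs. At 90% the median share of cluster 2 over hashtags was 14.3% instead of 8.38%.

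Leaving out each hashtag in turn (leave-one-out) gave 77.1% to 78.5% cardiomyocyte-like and 6.79% to 7.51% stromal-like cells. Cells without 1 hashtag (51.5%) stayed in each time. Cells of the left-out sample among them were not removed, so the ranges here can understate the dependence on single samples. Cluster 2 ranged from 11.6% to 15.8%, cluster 3 from 11.1% to 15.0% and cluster 5 from 12.3% to 12.8%. Higher and lower genes ranged over 67 to 69 and 78 to 85 for cardiomyocyte-like against other cells, 38 to 40 and 59 to 63 in cluster 2, 15 to 19 and 64 to 67 in cluster 3, and 89 to 89 and 8 to 9 in cluster 5.

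Cluster 6 had no counterpart under the strict filter, no filter, resolution 0.3, 3000 variable genes or readout lists allowed, nor cluster 1 at resolution 0.3, so these gave no value. The endothelial-like class rests on 63 cells, and stromal-like genes split 37 higher and 101 lower with the strict filter against 66 and 63. With no replicates, counting intervals say nothing about variation between cultures, and unremoved doublets and free RNA limit small differences between classes.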

Other observations

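No hypothesis test of this part was chosen only after the result was seen, since it reports values alone. HCN4 was not confined to cardiomyocyte-like cells. Epicardial-like cells had it at 60.2 CPM (200 counts) against 63.0 CPM, 1.05-fold lower with an interval of 0.911 to 1.21, although MYH6 was 13.1-fold and RYR2 6.92-fold lower there. The same class had KCNJ3 2.61-fold higher (1.89 to 3.51) and TBX18 at 228 CPM, which made up most of its pacemaker marker sum of 279 CPM. SHOX2 (4.21 against 41.1 CPM), TBX3 (8.42 against 62.8 CPM) and VSNL1 (1.80 against 29.4 CPM) were lower in this class than in cluster 2. The 12 cardiomyocyte markers, in contrast, stood in this class at a median of 9.65% of their level in cardiomyocyte-like cells. Only 25.6% of epicardial-like cells had 1 hashtag, against 39.7% to 54.7% in the other classes, so mixed barcodes were not ruled out for these values. STMN2, a neuronal microtubule gene, stood at 112 CPM in stromal-like cells, among their leading genes beside collagen.

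Pluripotency genes summed to 14.9 CPM in cardiomyocyte-like cells, and 34 of 20634 cells (0.165%, 0.114 to 0.230) had at least 3 of them. At least 3 neural genes were found in 48 cells (0.233%). Skeletal myogenic, immune and erythroid genes summed to 0.362, 0.769 and 1.098 CPM in cardiomyocyte-like cells, and 0 of 20634 cells had at least 3 genes of any of these lists, which allows a share of up to 0.0145% for cells with 3 detected genes at this depth and gives no limit for the share of a lineage.

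KCNJ2 was nearly undetected in cardiomyocyte-like cells, with 36 counts in 243090409 UMIs, so its ratios between cardiomyocyte clusters rest on few counts: 7 in cluster 2 and 0 in cluster 4. Its levels in the WFDC2/CLDN4 cluster rested on 263 counts and those in endothelial-like cells on 15. In cluster 2 the stress-related genes ANKRD1 (4056 CPM) and CCN2 (1084 CPM), singled out after their values were seen, were among the leading genes.

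Single hashtags differed in other classes as well. Endoderm-like cells made up 8.60% of Hashtag12 and stromal-like cells 31.1% of Hashtag1. Epicardial-like cells, of which 25.6% had 1 hashtag, ranged from 0% to 3.01%, the highest in Hashtag8. Cluster 1 ranged from 3.14% to 52.7% of cardiomyocyte-like cells with a median of 19.8%, cluster 4 from 1.14% to 43.5% with a median of 5.69%, cluster 6 from 0.687% to 25.5% with a median of 6.43%, and cluster 7 from 0.923% to 25.1% with a median of 7.49%.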
